A study of Arabidopsis thaliana with 48 samples.

How the data were processed

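Transcript levels were measured on 48 Affymetrix arrays, each hybridised with RNA from roots of Arabidopsis thaliana seedlings. Per the labels' protocols, 5 µg of total RNA per sample was labelled with a kit that primes at the 3' end and stained with streptavidin-phycoerythrin. The deposited table holds 1 column per array, and its values lie between 0 and about 15, the range of log2 probe set signals. The log base, the summary of probes into probe sets and the normalization are not given in the sources used here. The deposited log2 values had nearly the same mean on every array, from 7.69 to 7.70, while the medians ranged from 7.43 to 7.64, so the arrays share a mean but not their whole distribution. A constant offset between arrays that truly differed in total RNA would have been removed by such scaling, and all differences are therefore relative to the average probe set of an array.

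Samples were grouped by medium and time as their labels state, in 16 groups of 3. In 1 array, replicate 3 of the 1 h ACC group, the title and description name ACC whereas the source name and the agent name auxin. It was kept in the ACC group, and the counts without it are given with the results of that time. The labels number the replicates but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, part of which may be technical. No pair of arrays held identical values, and the highest correlation of 2 arrays was 0.996.

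Of 22810 probe sets, 64 control probe sets were left out of the tests, as were 7 with an exact 0 on some array, leaving 22739. Gene names came from the platform annotation. Among the probe sets that are not controls, 13513 had 1 gene symbol, 503 had several and 8730 were not listed in that table and are unnamed here. Symbols were updated through the Entrez identifier with a RefSeq gene table of the TAIR10.1 assembly, which matched 13436 probe sets. Only probe sets with 1 symbol were named, so several well-known ethylene, auxin and root hair genes could not be followed. Genes without a symbol carry their AGI code.

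Differences were computed with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 48 arrays, which gave 32 residual degrees of freedom and a prior of 3.99, followed by empirical Bayes moderation. The 8 contrasts of ACC minus control medium at the same time were each adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. Moderated F tests asked whether ACC had an effect at any of the 7 times after transfer, whether that effect differed between them, and whether control roots changed from 0 h. The median residual standard deviation of a probe set was 0.172 on the log2 scale and the median standard error of a difference was 0.140. The number of arrays limits this precision.

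Data were simulated from the real means and spreads, with 200 probe sets changed on ACC at 4 h alone and 200 others on both media at 8 h alone. The recoveries therefore do not describe effects that last over several times. The contrast at 4 h recovered 43.3% of changes of 0.5, 91.0% of changes of 1 and 97.0% of changes of 2 on the log2 scale. The F test over the times after transfer recovered 8.96%, 71.6% and 93.9%. The test for a differing effect recovered 8.96%, 65.7% and 93.9%, and the test of the control time course 41.8%, 89.6% and 97.0%.

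The design, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed before the data were examined. A list was tested where at least 3 of its genes were measured, which held for 10 lists. Each was tested at each time with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a set move one way and does not compare them with other genes. The adjustment covered 80 tests. A gene with several probe sets was represented by the one with the highest mean. Another 25 gene families were chosen later, before their values were seen, and 24 could be tested.

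The named genes were the 12 with the largest positive and the 12 with the largest negative peak difference among those past the F test whose 3 ACC arrays at the peak all lay above or below the 3 control arrays. To these were added the 3 largest in each direction at each time, up to 4 members of each list with the largest peak difference, 18 genes named whatever their values, and up to 10 genes in each direction that changed on control medium. Of the 18, only EIN3, GH3.3, LBD16 and EXPA7 were matched to a probe set with 1 symbol. Others are said to have been chosen after their values were seen.

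The alternatives were quantile normalization, a filter that kept 15102 probe sets above the 40th percentile of at least 3 arrays, an intensity trend with a robust prior, array weights, a replicate block, a minimum log2 difference of 1, a fit on the 6 arrays of a time, adjustment over the 8 contrasts together, subtraction of the 0 h difference, and leaving out each replicate number or each array of a time. Added after the data were seen were the omission of 4 arrays that stood apart, the inclusion of probe sets with a 0, the omission of each array for the F tests, and the GAPDH 3' minus 5' difference as a covariate. The 4 arrays were ACC replicate 3 at 0.5 and 2 h and control replicate 3 at 0 and 2 h. Counts under other splits of the samples, at most 100 per result, were obtained with the same model. Summaries and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.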

Results

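Transcript levels were measured in roots of 6-day-old Arabidopsis seedlings that had been grown under continuous light and moved on a nylon mesh to fresh medium. The new medium either lacked or contained 1 µM ACC (1-aminocyclopropane-1-carboxylic acid), the direct precursor of the gaseous hormone ethylene. Roots were collected within 5 min of transfer (0 h) and after 0.5, 1, 2, 4, 8, 12 and 24 h. Each of the 16 combinations of medium and time had 3 arrays, so 24 arrays came from each medium. The time-matched comparisons ask which transcripts differ in ACC-treated roots and when, and the control series shows what transfer and time alone do. Values are log2 signals as deposited, differences are ACC minus control with their standard error (SE), and n = 3 arrays per group throughout. Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

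Within 5 min of transfer no transcript passed the test between ACC and control roots. Of 22739 probe sets, 0 passed the threshold in limma, and 324 had an unadjusted p under 0.05 where 1137 would by chance. The 3 ACC arrays did not overlap the 3 control arrays for 6.83% of probe sets, where chance gives 10%. The later-responding genes RTE1 and ARL differed at 0 h by 0.11 ± 0.15 and -0.11 ± 0.28, less than their spread. Adjustment over the 8 contrasts together gave 3 probe sets.

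From 0.5 to 2 h on ACC, few transcripts passed the test, and how many did depended on single arrays and on the settings. ARL (ARGOS-LIKE), a growth regulator that lowers ethylene sensitivity, was already higher by 1.80 ± 0.28 at 0.5 h (adjusted p = 0.0024) and by 1.97 ± 0.28 at 1 h (3.92-fold, adjusted p = 0.000205). AT5G40590 was higher by 2.87 ± 0.57 at 0.5 h and by 3.06 ± 0.57 at 1 h, and AT5G48430, of the aspartyl protease family, by 3.00 ± 0.62 at 0.5 h. The transcription factor gene WRKY22 was higher by 2.28 ± 0.52 at 0.5 h and WRKY53 was 2.46-fold higher at 1 h (adjusted p = 0.0101). By 2 h the leading genes were AT2G39980, an acyltransferase of the HXXXD family (1.99 ± 0.30, adjusted p = 0.000373), AT2G43140 (1.81 ± 0.32) and AT5G01210 (1.64 ± 0.23).

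Other genes fell this early. At 0.5 h the expansin gene EXPB1 was lower by -1.39 ± 0.30, the pectin methylesterase inhibitor gene AT4G25250 by -1.73 ± 0.37 and AT5G60520 by -1.12 ± 0.26. At 1 h the lowest were AT1G23160, a member of the GH3 family (-1.81 ± 0.37), AT3G50640 (1.995-fold lower) and AT3G21680 (-0.97 ± 0.20). At 2 h AT5G66815, which encodes the peptide CEP5, was lower by -1.41 ± 0.29 and AT4G17280 by -1.01 ± 0.23.

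Over all probe sets, 56 passed at 0.5 h (27 higher, 29 lower), 63 at 1 h (48 higher, 15 lower) and 89 at 2 h (62 higher, 27 lower). After quantile normalization 15 of 44 were higher at 0.5 h, or 34.1% against 48.2% in the deposited values. The 3 ACC arrays did not overlap the 3 control arrays for 12.6%, 11.6% and 9.28% of probe sets, where chance gives 10%. At 1 h 12 of 25 were higher without control replicate 1 (48% against 76.2%), and at 0.5 h 44 of 55 (80.0%) without replicate 3 at all times. A fit on the 6 arrays of a time alone gave 0, 16 and 0 probe sets at 0.5, 1 and 2 h, and subtraction of the 0 h difference 0, 5 and 6. Other settings raised the counts: a replicate block as a fixed term to 119, 105 and 162, adjustment over the 8 contrasts together to 227, 179 and 214, and array weights to 139, 293 and 501. Another split of the same 6 arrays called more than the real one at each of these times (360, 97 and 123). The early counts also hung on single arrays. At 0.5 h the count was 5, 5 and 19 without control replicates 1, 2 and 3, and 676, 438 and 5 without ACC replicates 1, 2 and 3. At 1 h it was 25, 100 and 40 without the control replicates and 110, 15 and 28 without the ACC replicates, the last being the array with the auxin label. At 2 h it was 26 and 58 without control replicates 1 and 3, and 28, 23 and 364 without ACC replicates 1, 2 and 3.

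The single-gene calls of this period showed the same dependence. All 6 genes named at 0.5 h for their size (AT5G48430, AT5G40590, WRKY22, AT4G25250, EXPB1 and AT5G60520) lost their call without ACC replicate 3 (adjusted p = 0.0903 to 0.758), control replicate 1 (0.0748 to 0.213) or control replicate 2 (0.0642 to 0.119). Without control replicate 3, 4 of them did (0.0598 to 0.108), and WRKY22 did without ACC replicate 1 (0.054). Over all alternatives their adjusted p ran from 5.13e-07 to 0.758. At 1 h ARL, AT5G40590 and AT2G43140 kept their call without any single array of that time. AT1G23160, AT3G50640, AT3G21680 and WRKY53 lost theirs without control replicate 1 (0.0616 to 0.197). Smaller groups of these 4 did so without ACC replicates 1 (0.067), 2 (0.0602 to 0.119) and 3 (0.0758 to 0.145) and control replicate 3 (0.0596 to 0.101), and over all alternatives the 1 h values ran from 9.61e-06 to 0.664. At 2 h AT2G39980 and AT5G01210 kept their call in the same test. AT5G66815, AT4G17280, AT3G21680 or AT2G43140 lost theirs without ACC replicates 1 (0.143 to 0.297) and 2 (0.0875 to 0.301) and control replicates 1 (0.125 to 0.176) and 2 (0.0537 to 0.132), within a range of 9.81e-08 to 0.911 over all alternatives.

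**Figure D1:**
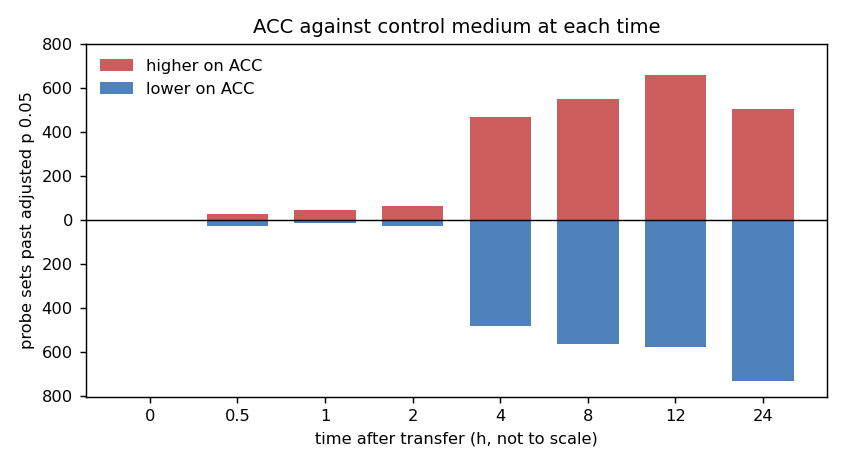
Probe sets past an adjusted p of 0.05 at each time after transfer (x axis, hours, not to scale), with the number higher on ACC drawn upward and the number lower drawn downward. The bars go from 0 at 0 h to 27 and 29 at 0.5 h, 469 and 482 at 4 h, and 658 and 576 at 12 h.

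From 4 h on, more transcripts passed than before, 951 to 1237 probe sets at each time against 56 to 89, a gap that was narrower without replicate 3 (418 at 2 h and 801 at 4 h), with array weights (501 and 1807) and with adjustment over the 8 contrasts together (214 and 767). Among probe sets with 1 gene symbol, a large gain was that of AT5G19890, a class III peroxidase gene, at 5.01 ± 0.71 at 12 h (32.3-fold, adjusted p = 1.32e-05). AT4G33720, which encodes a CAP domain protein related to PR-1, was higher by 4.67 ± 0.38 at 24 h (25.4-fold, adjusted p = 3.81e-10). AT4G39675 and AT5G40590 were higher by 4.54 ± 0.52 and 4.50 ± 0.57 at 12 h, and AT5G48430 by 4.49 ± 0.62 at 4 h. Further genes with large gains were AT1G49570, another class III peroxidase gene (4.35 ± 0.77 at 24 h), AT1G19530 (3.69 ± 0.55 at 8 h), the extensin-like gene AT1G26250 (3.41 ± 0.72 at 24 h), AT4G07820, also of the CAP family (3.24 ± 0.51 at 24 h), and AT3G15450 (3.22 ± 0.65 at 8 h). AT2G39980 reached 3.13 ± 0.30 at 8 h and AT4G21870, a small heat shock protein gene, 3.09 ± 0.48 at 4 h.

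The genes that fell most had varied functions. AT2G41730 was lower by -4.05 ± 0.88 (16.6-fold lower, adjusted p = 0.00328) and AT5G04120 by -3.96 ± 0.77 (adjusted p = 0.000967), both at 8 h. AT2G21640 and AT5G09570, which respond to oxidative and mitochondrial stress, were lower by -3.22 ± 0.67 at 12 h and -2.75 ± 0.61 at 24 h, and AT5G51440, a mitochondrial small heat shock protein gene, by -2.39 ± 0.60 at 8 h. AT5G66815 was lower by -3.01 ± 0.29 at 12 h (8.05-fold lower, adjusted p = 1.33e-08). The sugar transporter gene SWEET14 was lower by -2.55 ± 0.37 at 8 h, and AT1G47400, which encodes an IRONMAN peptide of the iron deficiency response, by -2.38 ± 0.55 at 12 h. The others were AT4G33550 (-2.74 ± 0.40 at 12 h), the dirigent family gene AT4G11210 (-2.38 ± 0.48 at 4 h), AT5G38020 (-2.34 ± 0.38 at 8 h) and the jacalin lectin gene JAL22 (-2.33 ± 0.53 at 8 h).

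**Figure D2:**
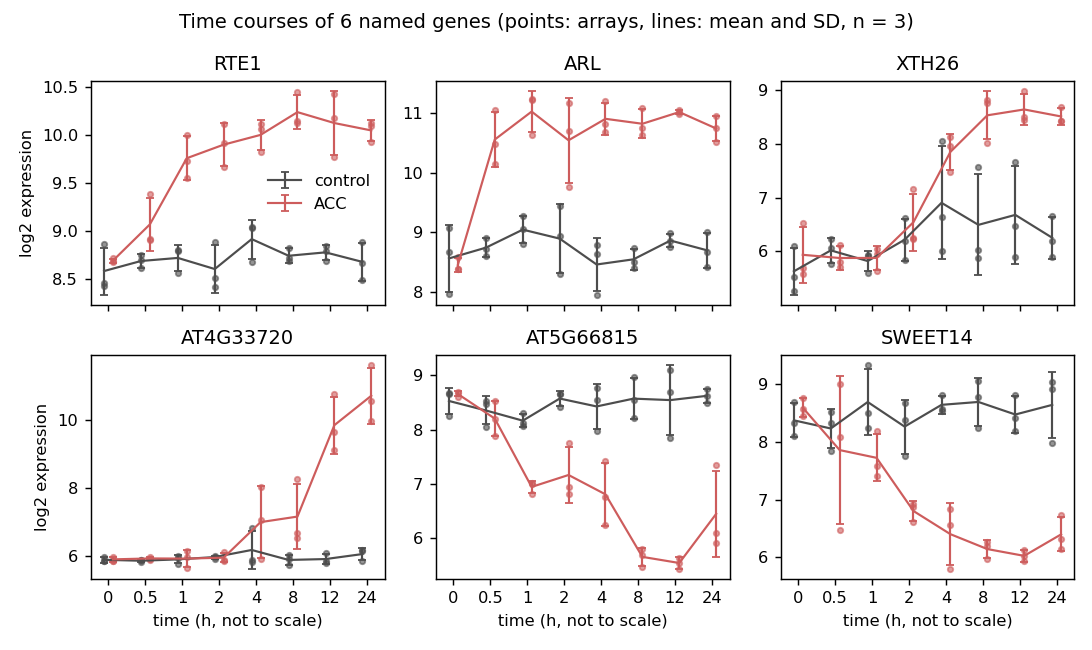
Log2 expression of RTE1, ARL, XTH26, AT4G33720, AT5G66815 and SWEET14 (y axes) against time after transfer (x axes, hours, not to scale), for control (grey) and ACC medium (red). Points are arrays, and lines join means with the SD of 3 arrays. ARL differs by 1.80 at 0.5 h, whereas AT4G33720 differs by -0.02 at 2 h and by 4.67 at 24 h.

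In all, 951 probe sets passed at 4 h (469 higher, 482 lower), 1113 at 8 h (550 and 563), 1234 at 12 h (658 and 576) and 1237 at 24 h (504 and 733). An absolute log2 difference of at least 1 was met by 304, 358, 407 and 375 of them, and the groups did not overlap for 19.5%, 24.5%, 24.2% and 22.0% of probe sets (10% by chance). The F test over all times after transfer called 3024 probe sets, 13.3% of those tested. From 4 to 24 h, array weights gave 1807, 3800, 3977 and 2356, subtraction of the 0 h difference 229, 312, 321 and 344, and the omission of replicate 1 at all times 52, 346, 227 and 203. Without single arrays the counts moved by over 1.5 times as follows. The 4 h count was 541 and 578 without control replicates 1 and 3 and 458 and 588 without ACC replicates 1 and 3, and the 8 h count was 728 and 713 without control replicates 1 and 2 and 686 and 603 without ACC replicates 2 and 3. The 12 h count was 645 without control replicate 1 and 785, 772 and 761 without ACC replicates 1, 2 and 3, and the 24 h count was 494 and 788 without control replicates 1 and 3 and 607 without ACC replicate 3.

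Of the 70 named calls at all times, 49 held without each single array of their time, and 28, 37 and 64 held when replicate number 1, 2 or 3 was left out throughout. Over all alternatives the adjusted p of late calls reached 0.28 for AT1G26250, 0.249 for AT1G47400, 0.252 for AT4G11210, 0.337 for AT5G19890 at 4 h, 0.171 for AT5G64100, 0.188 for BHLH101, 0.138 for RCA, 0.11 for AT5G09570 and 0.1 for Prx37. AT5G04120 reached 0.292, 0.0614 and 0.0989 at 4, 8 and 12 h, AT2G21640 0.144 and 0.195 at 8 and 12 h and AT2G41730 0.101 at 8 h. Smaller excesses were those of AT4G33550 at 24 h (0.0864), AT3G15450 (0.0762), XTH26 at 24 h (0.0583), EXPA4 at 8 h (0.0515), AT5G40590 at 4 h (0.0509) and AT4G07820 (0.0504). The late calls lost without a single array were LHCB4.2 and AT5G39580, given with their lists, AT2G41730, whose adjusted p was 0.0575, 0.106 and 0.0751 at 4 h without ACC replicates 1 and 3 and control replicate 1, JAL22 at 8 h (0.0769 without ACC replicate 2 and 0.0561 without control replicate 3), and AT5G51440 at 8 h (0.0558 without control replicate 1, 0.05 without control replicate 2 and 0.0675 without ACC replicate 3). AT2G21640 at 24 h reached 0.0699 without control replicate 3 and 0.0947 without ACC replicate 3. AT2G41730 at 12 h had 0.131 and 0.136 without control replicates 1 and 2 and 0.0982 and 0.0722 without ACC replicates 2 and 3. Over all alternatives the adjusted p of these calls ran up to 0.415 for AT2G41730 at 12 h, 0.25 at 4 h, 0.199 for JAL22, 0.253 for AT5G51440 and 0.145 for AT2G21640 at 24 h, and their lowest values were 7.37e-06, 0.000211, 0.000151, 1.65e-05 and 0.000464.

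A sign of RNA quality moved with the treatment. The 3' minus 5' log2 difference of the GAPDH control probe sets was higher on ACC by 0.294 on average over the 7 times after transfer (higher at 7 of 7 times, permutation p = 8e-05, adjusted p = 0.00024, two-sided, 100000 permutations). That of ubiquitin was higher by 0.076 (6 of 7 times, permutation p = 0.016, adjusted p = 0.024) and that of actin by 0.092 (6 of 7 times, permutation p = 0.16). At 24 h the GAPDH difference was 1.21 ± 0.19 on ACC and 0.703 ± 0.355 on control medium (SD, n = 3). With it as a covariate, a choice made after it was seen, 1879 probe sets passed the F test and the counts from 0.5 to 24 h were 35, 22, 92, 715, 975, 1199 and 776. Of the 70 named calls 8 were lost (adjusted p = 0.054 to 0.164 with the covariate), with differences that kept their direction. At 0.5 h WRKY22 went from 2.28 ± 0.52 to 2.196 ± 0.526 and AT5G60520 from -1.12 ± 0.26 to -1.10 ± 0.26. At 1 h AT5G40590 went from 3.06 ± 0.57 to 2.67 ± 0.61, AT1G23160 from -1.81 ± 0.37 to -1.41 ± 0.37 and AT3G21680 from -0.97 ± 0.20 to -0.91 ± 0.22, and AT3G50640 and WRKY53 stood at -0.93 ± 0.20 and 1.13 ± 0.27. AT5G39580 went from 2.56 ± 0.71 to 2.122 ± 0.794 at 24 h. Of the gene lists, lateral root formation at 1 h (adjusted p = 0.246) and shoot photosynthesis at 8 h (0.204) lost their call, and root hair growth (0.0122) and class III peroxidases (0.0491) at 1 h and auxin response at 8 h (0.0402) gained one, within ranges over all alternatives of 0.00113 to 0.565, 0.0147 to 0.251, 0.0122 to 0.42, 0.0491 to 0.681 and 0.0402 to 0.625.

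In the list of 21 ethylene perception and signalling genes, 2 of the 5 measured members rose and none fell. Of the planned lists of 21 ethylene biosynthesis genes and 28 ERF and EDF transcription factor genes, 0 members were measured. RTE1, a membrane protein gene whose product acts with the receptor ETR1 to hold the response down, was higher by 1.04 ± 0.15 at 1 h and by 1.50 ± 0.15 at 8 h (2.82-fold, adjusted p = 4e-08). ARL was higher at every time after transfer, with a peak of 2.43 ± 0.28 at 4 h (5.39-fold, adjusted p = 5.96e-07). EIN3, the central transcription factor of the pathway, differed by at most 0.22 ± 0.16 and RTH, related to RTE1, by -0.16 ± 0.13, neither past the threshold. ETP2, an F-box protein gene named after its values were seen, differed by at most 0.12. Adjusted over the list alone, the count was also 2. The list passed camera as higher from 0.5 to 24 h, with an adjusted p of 9.03e-06 at 1 h (0.00132 with an estimated correlation). Only RTE1 and ARL passed alone, and the list was not tested without them. Its median was 0.216 at 0.5 h, 0.153 at 1 h, 0.020, 0.049, 0.063 and 0.069 at 2, 4, 8 and 12 h, and 0.18 at 24 h. At 0.5 h the adjusted p was 0.0131, and 0.0573 with an estimated correlation, which ended that call, as did the omission of replicate 1 (0.177) or 2 (0.0539) (range 0.000369 to 0.177 over all alternatives).

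In the list of genes for loosening and extending the cell wall, the measured members fell as a group. Of the 8 measured members of the list, 6 were lower at some time and 0 were higher, although adjusted over the list alone 1 was higher and 2 were lower at 0.5 h. XTH21, a xyloglucan endotransglucosylase gene, was lower by -2.07 ± 0.25 at 12 h (4.21-fold lower, adjusted p = 6e-07). The expansin genes EXPB1, EXPA4 and EXPA8 were lower at 8 h by -2.05 ± 0.30, -1.54 ± 0.32 and -1.13 ± 0.19. XTH18 and XTH20, named after their values were seen, did not pass at any time. Their largest differences were upward, 1.12 and 0.39 at 0.5 h (adjusted p in limma 0.0712 and 0.7). At 8 h the median of the list was -1.13, with 6 members past the threshold over all genes and 6 adjusted over the list alone, and camera gave an adjusted p of 2.57e-08 (0.000195 with an estimated correlation). Wider families, looked at later, moved less. Their medians at 8 h were -0.197 for 18 expansin and expansin-like genes and -0.069 for 9 xyloglucan endotransglucosylase genes. The list passed from 0.5 h on, but at 0.5 h its adjusted p of 0.0458 became 0.135 with an estimated correlation, 0.144 and 0.149 without replicates 1 and 2, 0.05 without the 1 h ACC array that carries the auxin label and 0.0669 without the 4 arrays that stood apart, with a range of 0.0116 to 0.149 over all alternatives. The GAPDH 3' minus 5' difference was higher on ACC at each of these times. With it as a covariate the list lost none of its calls. XTH21 then stood at -2.04 at 12 h, and EXPB1, EXPA4 and EXPA8 at -1.76, -1.45 and -0.97 at 8 h.

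Some class III peroxidase genes, whose products oxidise phenolics in the cell wall, rose from 4 h. Of the 10 measured members of the list, 4 were higher at some time and 0 lower, while AT5G66390, a peroxidase gene outside the list named after its values were seen, was lower by -1.02 at 24 h. Prx37 was higher by 2.34 ± 0.40 at 12 h (adjusted p = 0.000203), AT4G11290 by 1.51 ± 0.17 at 12 h (adjusted p = 3.34e-07), AT5G64100 by 1.50 ± 0.30 at 12 h and AT5G39580 by 2.56 ± 0.71 at 24 h. The last lost its call without control replicates 1 (adjusted p = 0.183) or 3 (0.078) or ACC replicates 2 (0.0538) or 3 (0.162), in a range of 0.00153 to 0.378 over all alternatives. At 12 h the median was 1.103, and 3 members passed over all genes and 5 adjusted over the list alone. The list passed camera at 4, 8, 12 and 24 h, with an adjusted p of 2.15e-06 at 12 h. With an estimated correlation the adjusted p was 0.0719, 0.0547, 0.0323 and 0.0795, so that only the 12 h call held. At each of these 4 times the GAPDH 3' minus 5' difference was also higher on ACC. With it as a covariate and the preset correlation the list lost none of its calls. Prx37, AT4G11290 and AT5G64100 then stood at 2.34, 1.59 and 1.54 at 12 h, while AT5G39580 at 24 h lost its own call.

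**Figure D3:**
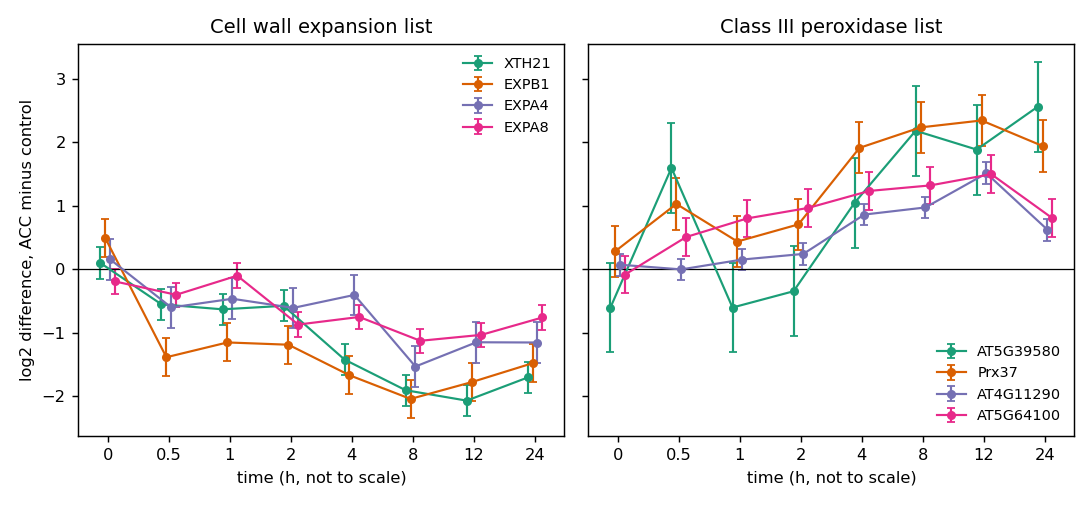
Log2 difference, ACC minus control (y axis), against time after transfer (x axis, hours, not to scale) for 4 genes of the cell wall expansion list (left) and 4 of the class III peroxidase list (right). Points are differences of group means and bars their SE, with n = 3 arrays per group. XTH21 reaches -2.07 and Prx37 2.34 at 12 h.

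Of the 4 measured root hair growth genes, XTH26 rose, by 2.04 ± 0.41 at 8 h and 2.26 ± 0.41 at 24 h (4.80-fold, adjusted p = 0.000424). EXPA7 and EXPA18, expansin genes of growing root hairs, had their largest differences at 0.5 h (-1.02 ± 0.37 and -1.08 ± 0.37) and did not pass at that time, although EXPA7 passed the F test over the times (adjusted p = 0.0307) and without ACC replicate 1 of that time their adjusted p was 0.0153 and 0.0206 (over all alternatives up to 1). AT2G14760, a basic helix-loop-helix gene of the same list, differed by at most 0.33 ± 0.13. Adjusted over the list alone, 2 members were lower at 0.5 h. At 24 h 1 member passed, also adjusted over the list alone, and the list passed camera as higher (adjusted p = 0.0258), a call lost without replicate 2 (0.0929) or with an estimated correlation (0.297), in a range of 0.0183 to 0.297 over all alternatives. Without replicate 3 the list also passed at 4 h (0.0151), 8 h (0.00736) and 12 h (0.0384), and without replicate 1 it passed as lower at 0.5 h (0.0143). The upper ends of the ranges at these times were 0.567, 0.607, 0.783 and 0.42.

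None of the measured genes of the planned auxin lists passed at a single time, but most of the listed ones were not measured. The measured ones were 9 of 29 auxin response genes, 5 of 25 biosynthesis genes and 1 of 20 transport genes. Outside these lists AT1G23160, of the GH3 family, passed as lower at 1 h. Of the 9 measured auxin response genes, 0 passed limma at any single time (1 at an unadjusted p under 0.05), and 0 adjusted over the list alone. IAA29, named after its values were seen, passed the F test over the times (adjusted p = 0.0372) with a largest difference of 0.36 at 8 h. GH3.3, an early auxin-induced gene, differed by 0.98 ± 0.56 at 0.5 h, LBD16 by 0.45 ± 0.22, LBD29 by -0.45 ± 0.23 at 1 h and WES1 by 0.40 ± 0.22 at 8 h. The list passed camera at 0 h with a median of -0.186 (adjusted p = 0.00835) and at 0.5 h with a median of 0.198 (0.0168), and both calls were lost with an estimated correlation (adjusted p = 0.321 and 0.406). The 0 h call was also lost without the 4 arrays that stood apart (0.929), without replicate 3 (0.857) and with fry (0.449), and the 0.5 h call without replicate 1 (0.802) or 2 (0.126) and with fry (0.237). Without replicate 3 the list passed at 1 h (0.000964) and 8 h (0.0482). Over all alternatives the adjusted p ran from 0.00305 to 0.929 at 0 h, 9.02e-08 to 0.802 at 0.5 h, 0.000964 to 0.807 at 1 h and 0.0402 to 0.625 at 8 h. Of 5 auxin biosynthesis genes, none passed (2 at an unadjusted p under 0.05). YUC6 and YUC4, flavin monooxygenase genes, differed by at most -0.30 ± 0.16 and -0.26 ± 0.13, YUC11 by 0.26 ± 0.14 and AT2G04400 by 0.92 ± 0.31. Adjusted over the list alone, 1 passed at 0.5 h.

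The 4 lateral root genes LBD16, LBD29, PUCHI and CR4 gave 0 calls in limma (2 at an unadjusted p under 0.05) and, adjusted over the list alone, 1 at 0.5 h and 0 at 1 h. The list, lower by camera at 1 h (adjusted p = 0.0179), had 0.105 with an estimated correlation and 0.565 without replicate 1. PUCHI differed by -0.47 ± 0.19 at 1 h and CR4 by -0.32 ± 0.11 at 0.5 h. Among markers of another organ, the photosynthesis genes RCA and LHCB4.2 were higher at 12 h by 1.32 ± 0.28 and 0.65 ± 0.19, and SBPASE differed by at most 0.20 ± 0.18. Adjusted over the list alone 2 passed as well. LHCB4.2 lost its call without control replicates 1 (adjusted p = 0.0937) or 2 (0.189) or ACC replicates 1 (0.14) or 2 (0.108), in a range of 0.0017 to 0.341. Their list passed camera at 8 h (0.0258) and 12 h (0.00869), and neither call held with an estimated correlation (adjusted p = 0.251 and 0.141) or without replicate 2 (0.0788 and 0.126), nor the first without replicate 3 (0.0641). At 0 h the list passed without replicate 1 (0.0417), without replicate 3 (0.0128) and without the 4 arrays that stood apart (0.00567).

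Of 4 iron deficiency genes, BHLH101, a transcription factor gene of that response, fell by 1.91 at 24 h (SE 0.45, adjusted p = 0.00752), while AT3G13610 differed by 1.41 ± 0.49 at 4 h (past the F test alone, adjusted p = 0.0383), AT3G12900 by 0.46 ± 0.27 and BGLU42 by -0.16 ± 0.14. The list passed at 0 times, its lowest adjusted p being 0.416 by camera with the preset correlation, 0.237 by fry and 0.146 over all alternatives. At 24 h 1 member was higher and 1 lower adjusted over the list alone. The flavonoid genes UGT78D1, UGT78D2 and DFR gave 0 calls (1 at an unadjusted p under 0.05). Lists with under 3 measured genes were not tested as groups: STZ of the touch response, the defensin genes PDF1.2 and PDF1.2b, the mitotic kinase genes AUR1 and AUR2, and WAG2, TRY, PRL, GI and AT3G10040 did not pass at any single time. The clock gene GI passed the F test over the times (adjusted p = 0.0378), with a largest difference of -0.37 at 8 h. Over the 10 tested lists, 24 of 80 tests passed with the preset correlation, 13 with an estimated one and 22 with fry. Where a list passed, its median, mean and tested direction had the same sign, also after quantile normalization.

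Most peaks fell late, and part of the calls recurred from time to time. Among the 779 probe sets past the F test with an absolute difference of at least 1, 423 had a positive and 356 a negative peak. For 713 of them (91.5%) the peak lay at 4 h or later, with 178 at 4 h, 145 at 8 h, 187 at 12 h and 203 at 24 h, against 39, 18 and 9 at 0.5, 1 and 2 h. First calls came at 4 h for 313 and at 8 h for 173. The calls at different times overlapped far beyond independent lists: 408 probe sets were higher at both 8 and 12 h where 15.9 would be expected, and 37 of the 48 higher at 1 h were also higher at 4 h. The time-matched contrasts share no arrays. They do share 1 estimate of the spread per probe set, so the overlap expected of independent lists may be too low. Of the 469 higher at 4 h 200 were higher at 24 h, of the 482 lower 233 were, and of the 15 lower at 1 h 5 were lower at 24 h. Of 2318 probe sets that passed at some time from 4 to 24 h, 161 were higher and 174 lower at each of the 4 times, and 0 passed in opposite directions at 2 times.

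How far each array had moved along the late response was measured as a score, the slope of its differences from the mean of the control arrays of its time, itself left out, on the mean ACC effect at 4 and 8 h, or for these times on 2 other times. The 24 control arrays lay between -0.168 and 0.180 and the ACC arrays from 4 h on between 0.649 and 1.05. At 0.5 h the ACC arrays had scores of 0.33, 0.171 and 0.39, of which that of replicate 2 (0.171) lay within the range of the control arrays. At 1 h the ACC arrays had scores of 0.373, 0.462 and 0.402, and at 2 h 0.590, 0.783 and 0.206, the last for replicate 3.

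**Figure D4:**
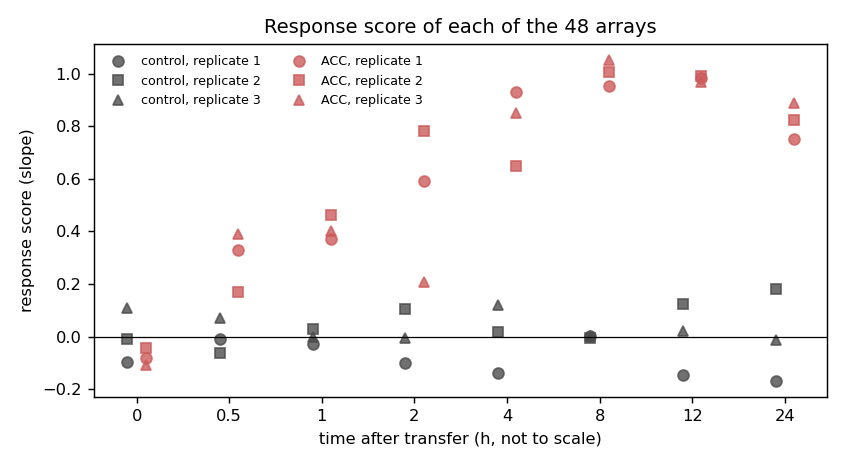
Response score (y axis, a slope without unit) of each of the 48 arrays against time after transfer (x axis, hours, not to scale), with control arrays in grey, ACC arrays in red and a symbol for each replicate number. ACC arrays at 0 h lie among the controls, those from 4 h on lie above 0.64, and ACC replicate 3 at 2 h lies at 0.206.

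Few probe sets passed the test for an ACC effect that differed between times, which does not show that the effect was steady in the others. Only 3024 passed the F test for any ACC effect, and the simulation recovered 8.96% of changes of 0.5, made at 4 h alone, in the test for a differing effect. A difference between the 7 times was found for 159 probe sets, 0.699% of those tested (1736 at an unadjusted p under 0.05). The most pronounced among named genes was AT4G33720, whose difference was 0.07 ± 0.38 at 0.5 h, 0.82 ± 0.38 at 4 h and 3.95 ± 0.38 at 12 h (adjusted p of the difference = 1.49e-07). AT5G66815 went from -0.15 ± 0.29 at 0.5 h to -3.01 ± 0.29 at 12 h, and RTE1 from 0.38 ± 0.15 to 1.50 ± 0.15 at 8 h. ARL showed no such difference between times (adjusted p = 1). Array weights raised the count to 870 and a replicate block to 255 as a fixed and 264 as a random term, and without replicate 1 at all times it was 5. Without single arrays the count fell by over 1.5 times, to 98 and 94 without control replicates 1 and 3 at 0.5 h, 105 and 102 without control replicates 1 and 3 at 1 h, 103 without ACC replicate 3 at 1 h, 104 without control replicate 1 at 24 h and 87 without ACC replicate 3 at 24 h.

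On control medium, no change between 0 and 24 h after transfer was detected. The F test called 0 probe sets in limma, with a lowest adjusted p of 0.59, so no gene was named for this comparison. An unadjusted p under 0.05 was found for 529 probe sets where 1137 would by chance, so the test was conservative here. The simulation recovered 89.6% of changes of 1, made at 8 h alone, in this test, but it drew independent errors, and the recovery may be lower in the real data. Without control replicate 1 or 2 at 1 h the count was 2 and 1, and without the 4 arrays that stood apart it was 27. Among the lists, class III peroxidases at 2 h (adjusted p = 0.0255), root hair growth at 4 h (0.012) and iron deficiency at 24 h (0.0251) were higher than at 0 h by camera, with medians of 0.393, 0.858 and 0.394. With an estimated correlation the adjusted p was 0.571, 0.392 and 0.3, and 0 of 70 list tests passed.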

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

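The tests of a wrong label, of an exchange of samples and of degraded RNA, and the omission of 4 arrays, were chosen after the results they concern had been seen. The others were written down first.

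The effect of ACC differed between the 7 times after transfer for 159 probe sets, which draws attention because a difference between groups was itself tested. Among the named genes the adjusted p in limma was 1.49e-07 for AT4G33720, whose difference was 0.07 at 0.5 h and 4.67 at 24 h, 0.000483 for AT5G66815 (-0.15 at 0.5 h, -3.01 at 12 h), 0.000845 for AT4G39675 (0.80 at 0.5 h, 4.54 at 12 h) and 0.00213 for the peroxidase gene AT4G11290. It was 0.00401 for AT2G39980, 0.00986 for the peroxidase gene AT5G19890, 0.0125 for XTH21, 0.0176 for AT4G33550, 0.0191 for AT4G07820, 0.0336 for XTH26 and 0.0427 for RTE1. Each of these 11 genes had its largest difference at 8, 12 or 24 h, with the 3 ACC arrays all on 1 side of the 3 control arrays there. Except for AT4G11290, XTH21, XTH26 and RTE1, this separation was a condition of being named and so adds no evidence. These exceptions were named for the size of the same peak difference in the same arrays, so the separation is no independent evidence for them either.

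A signal appeared in a probe set that the tests left out because it holds exact zeros. This probe set, which has no gene name here, had a mean of 14.7 in the 8 ACC arrays with replicate number 3, a level near the top of the scale, and 0 in each of the other 40 arrays. No explanation was tested, and the pattern follows the replicate number and the medium together.

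ACC replicate 3 at 2 h lay near the control arrays. Its response score was 0.206, against 0.590 and 0.783 in the other ACC arrays of that time and a highest control score of 0.180 (control SD 0.0900), and without it 364 probe sets passed at 2 h instead of 89. An exchange with control replicate 3 of that time was excluded, because the score of that array was -0.004. A weaker response of all ACC replicate 3 arrays was excluded as well, since that array had the lowest score of its group at 1 of 5 other times. A single wrong label stays open: the score lies above all control scores but by less than their SD, a margin set after the value was seen, and a slower response of these roots, for which no test was made, is a candidate explanation too.

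ACC replicate 3 at 0.5 h stood apart from all other arrays, with a median correlation of 0.944 where the next lowest was 0.966. The actin probes showed no sign of degraded RNA: their 3' minus 5' difference was 3.29, within the range of the other arrays, whose highest was 4.05. This does not exclude degradation, since only a value above all other arrays would have counted for it. The GAPDH difference of this array was 0.998, the highest at 0.5 h, where the others ran from 0.427 to 0.957, but below the highest of all arrays (1.405). Scaling that keeps the order of the values was excluded, because the median rank correlation was 0.947 and still the lowest (next 0.967). What set this array apart may be technical or a difference between the plants, and no test made here separates these. Without it 5 probe sets passed at 0.5 h instead of 56.

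ACC replicate 3 at 1 h carries both an ACC and an auxin label. If these roots had been on auxin medium, the auxin response genes should have been at least 1 higher than in the other ACC arrays of that time, and they were higher by 0.18, under the bound of 0.5 set beforehand. GH3.3 was at 9.35 against 8.54 and 8.27. Its score of 0.402 lay above the highest control score of 0.180, which goes against roots on control medium. No other array carried an auxin label, so whether auxin without ACC could give such a score was not tested. The highest mean of the auxin response list among all arrays was found elsewhere, in control replicate 1 at 1 h (8.07, with GH3.3 at 10.94), followed by ACC replicate 1 at 0.5 h (7.92, with GH3.3 at 9.94).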

How the results depend on the processing

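The omission of 4 arrays that stood apart, the inclusion of probe sets with a 0, the omission of each array for the F tests and the named genes, and the GAPDH covariate were chosen after the data were seen. No call of a named gene or of a list reversed its direction. The balance of higher and lower calls did turn: at 0.5 h the higher share was 48.2%, but 80.0% without replicate 3 and 57.6% with array weights, at 1 h it was 76.2%, but 48% without control replicate 1, at 2 h 69.7%, but 48.8% without replicate 3, at 4 h 49.3%, but 65.4% without replicate 1, and at 24 h 40.7%, but 50.1% with a minimum difference of 1. Shares near one to one also crossed that line under other settings at 4, 8 and 12 h. The cause was not tested. Over all settings, 268 counts stayed within 1.5 times the reported count and 118 moved further. For the named genes 1444 comparisons stayed on their side of the threshold, 165 lost the call and 13 gained one, and for the list tests the numbers were 837, 30 and 13. Quantile normalization, the filter on dim probe sets, the trended robust prior and the inclusion of zeros moved no count by over 1.5 times: for the F test over the times the first 3 of these gave 3084, 2863 and 2992, against 3024. The median difference of all probe sets shifted by at most 0.02 in either direction.

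Array weights raised the counts from 0.5 to 24 h to 139, 293, 501, 1807, 3800, 3977 and 2356, the F test to 5846, the differing effects to 870 and the control course to 1. The replicate number as a fixed term gave 119, 105 and 162 at 0.5, 1 and 2 h and 255 differing effects, and as a random block 134, 110, 176 and 264. The replicate numbers were not treated as pairs, since not every pair was correlated above 0.1. Of 24 pairs with the same number and time, 16 had deviations from their group means correlated above that, in a range of -0.265 to 0.41, all 3 pairs at 1, 2 and 8 h among them. Even so, 15 of 24 ACC arrays were most correlated with the control array of their own number, out of 3 at their time. The reported counts and those of other splits do not take up what arrays of the same number may share. The cause of the shifts in counts was not tested.

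A minimum log2 difference of 1 left, by its construction, 24, 33, 29, 304, 358, 407 and 375 from 0.5 to 24 h and 779 for the F test. The fit on the 6 arrays of a time gave 0, 16 and 0 at 0.5, 1 and 2 h, but 1368 at 8 h and 1282 at 24 h, and the cause was not tested. Adjustment over the 8 contrasts together gave 3 at 0 h and 227, 179 and 214 at 0.5, 1 and 2 h. Subtraction of the 0 h difference, which adds the spread of 6 more arrays, gave 0, 5, 6, 229, 312, 321 and 344.

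The choice of the 4 arrays that stood apart did not follow their correlation with the other arrays alone. ACC replicate 3 at 24 h was kept with a median correlation of 0.9664, and ACC replicate 3 at 2 h was left out with 0.9725. Without the 4 arrays the counts were 237 at 1 h, 417 at 2 h, 1518 at 4 h and 1893 at 24 h, with 250 differing effects and 27 in the control course. With the GAPDH covariate they were 35 at 0.5 h, 22 at 1 h, 776 at 24 h and 1879 for the F test. The cause was not tested in either case. With an estimated correlation 13 list tests passed instead of 24. A minimum of 0.5 in the timing set gave 2181 probe sets, 1907 of which peaked at 4 h or later, against 713 of 779.

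Leaving out each replicate number or single array gave these ranges, whose upper ends exceed the reported counts at 0.5, 1, 2 and 24 h, in the F tests and in the list tests and so do not follow from fewer samples: 0 to 0 at 0 h, 0 to 676 at 0.5 h, 3 to 110 at 1 h, 2 to 418 at 2 h, 52 to 808 at 4 h, 303 to 873 at 8 h, 227 to 1122 at 12 h and 203 to 1322 at 24 h. The F test ranged from 950 to 3338, the differing effects from 5 to 199, the control course from 0 to 2, the list tests from 18 to 28 and the calls of named genes, 70 as reported, from 28 to 64. Where this left 2 arrays in a group, their spread was pooled with the other groups. Signal near background limits the dim probe sets, and 15102 of 22739 passed the filter on them.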

Other observations

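The gene families, both added lists and the tests of each were chosen after the data had been opened, the families before their values were seen. The membership of 3 families (bZIP, cytochrome P450 and defensin genes) was corrected afterwards, because other genes share their prefix. The splits of the samples were planned.

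Families of genes that carry a common name were looked at beside the planned lists, and their members are named here after their values were seen. Of 18 measured expansin and expansin-like genes, 6 were lower at some time, among them EXPB3 by -1.88 at 24 h, and 1, EXLB1, was higher, by 1.12 at 12 h. The family was lower by camera at 2 h (adjusted p = 0.000484) and 8 h (0.0393), with 0.0777 and 0.213 under an estimated correlation. The 9 xyloglucan endotransglucosylase genes, of which XTH26 rose and 3 fell, gave no call as a group by camera, while fry called them at 1 h (adjusted p = 0.0291) and 2 h (0.0451). Of 6 WRKY genes 4 rose: WRKY22 at 0.5 h, WRKY53 at 1, 12 and 24 h, and WRKY47 (0.54) and WRKY20 (0.38) at 12 h. The family passed camera at 0.5 h (0.0340) and 1 h (0.0237), and had 0.0777 at both times with an estimated correlation. The 7 Aux/IAA genes were higher as a group by camera at 8 h (0.0393, with an estimated correlation 0.198), with 0 past the threshold alone in limma (5 at an unadjusted p under 0.05 at some time). Of 5 CLE peptide genes, CLE41 (-0.96 at 8 h) and CLE26 (-0.46 at 24 h) fell, and the family passed camera at 8 h (0.0393, with an estimated correlation 0.198).

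In families that camera did not call, single genes changed. Fry called some of these: the bZIP genes at 1, 2, 4 and 24 h (adjusted p = 0.00633 to 0.0291), the tau and phi glutathione transferases from 4 to 24 h (0.00633 to 0.0291), and the serine carboxypeptidase-like genes at 4 h (0.0216) and 24 h (0.00671). Of 14 sugar transporter genes SWEET14 and SWEET13 fell, the latter by 1.95 at 8 h (adjusted p in limma 1e-05). Of 7 bZIP genes bZIP44 (1.01 at 2 h) and bZIP48 (0.62 at 24 h) rose. Among 24 cytochrome P450 genes 4 rose, with CYP718 (1.74 at 12 h) and CYP71B29 (1.18 at 4 h) foremost, and among 47 glycosyltransferase genes 4 rose and 3 fell, from UGT71C3 (1.16 at 12 h) to UGT84A1 (-1.23 at 24 h). BGLU46 was higher by 1.66 and the defensin gene PDF2.5 by 1.60 at 24 h. GSTU25 was lower by -2.02 at 8 h, RALFL27 by -1.57 and TBL36 by -1.24 at 24 h, BGLU28 by -1.37 at 12 h and the tubulin gene TUB1 by -0.92 at 4 h. None of 8 autophagy and 5 response regulator genes passed in limma, and 1 of each had an unadjusted p under 0.05 at some time. Over 24 families, 6 of 192 tests passed with the preset correlation, 0 with an estimated one and 26 with fry.

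Because AT2G21640, AT5G09570 and AT5G51440 fell, other genes known from mitochondrial stress may have fallen with them. Of a list of 12 such genes 5 were measured, and all 5 were lower at 8 h, with a mean of -1.55: AT2G04050 (-2.08), AT5G43450 (-1.65), NDB4 (-1.53), AT2G04070 (-1.30) and AT2G32020 (-1.19). None passed alone in limma at 8 h, and AT5G43450 passed at 4 h (-2.18, adjusted p = 0.0437). Camera with an estimated correlation gave a p of 0.0841 for the list, so the question stays undecided with 5 genes. AT2G04050 and AT5G43450 had been seen earlier as low in control replicate 3 at 0 h.

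Low values of dirigent and peroxidase genes at 24 h led to the hypothesis that genes of the endodermal barrier fell. Of 20 listed genes 6 were measured, and their mean at 24 h was -0.523 (camera with an estimated correlation p = 0.0248, adjusted over both added lists 0.0496, a margin that may not last under another choice). The GAPDH 3' minus 5' difference at 24 h was 1.205 on ACC and 0.703 on control medium, and this list was not tested with it as a covariate. At 24 h AT2G48130, the peroxidase gene AT5G66390 and the receptor kinase gene GSO1 were lower by -1.09, -1.02 and -0.67 and passed limma alone, and AT1G44970 (-0.82) and AT1G61590 (-0.16) did not. The subtilase gene SBT4.12 went the other way, higher by 1.22 at 8 h.

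The counts were set against other splits of the same samples. For a single time the 6 arrays make 10 splits, too few for a share under 0.05. At 0 h all 10 gave 0. As many probe sets as the real split, that one included, were called by 2 splits at 0.5 h (56 real, highest other 360), 2 at 1 h (63 and 97) and 2 at 2 h (89 and 123), and by 1 split at 4 h (951 and 0), 8 h (1113 and 0), 12 h (1234 and 0) and 24 h (1237 and 1). The highest other split put control replicates 1 and 3 with ACC replicate 1 at 0.5 and 1 h, and control replicates 1 and 3 with ACC replicate 3 at 2 h. At 0.5 h its count is several times the real one and points to a structure of the samples other than the medium.

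Splits of the media within all times were drawn 100 times. For the F test over the times 1 of 100 was as large (3024, highest other 2137) and for the gene lists 1 of 100 (24, highest other 18). In both cases this was the real split itself, and 100 splits cannot give a smaller share. Splits that mix the media also add the ACC effect to the residual spread, which can lower their counts. Chance is therefore made unlikely for both but not excluded. For the effect differing between times 4 of 100 were as large as the real 159 (highest other 2213). Such splits keep the real grouping at some times and break it at others, a structure that by itself turns a steady ACC effect into a difference between times, so they do not test that difference and exclude nothing for it. For the time course on control medium 100 of 100 splits of the 24 control arrays gave as many as the real 0 (highest other 684), an outcome that a count of 0 fixes in advance and that decides nothing.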
